A study of Mus musculus with 11 samples.

How the data were processed

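The series holds MERFISH measurements of 11 sections of mouse hippocampus, in groups of 3 (CONTROL), 2 (MELANOMA), 3 (CONTROL ICI) and 3 (MELANOMA ICI). Per the labels' protocols, male mice of 10 to 12 weeks received 500000 D4M-3A.UV2 cells in the skin of both sides or none. After 1 week of engraftment they received isotype antibodies or anti-CTLA-4 (1 mg, 3 doses a week) with anti-PD-1 (200 µg, 2 doses a week) for 3 weeks, and 10 µm sections of embedded brain were hybridised and gel-embedded. Each section has 1 table with a line per segmented object and 17 columns. The software, its version, the segmentation settings and the probe panel are not given in the sources used here.

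Transcript counts per object are raw counts summed over all probes, per the file headers, with no normalization that the headers or the labels state. Anisotropy is a deposited ratio of the long to the short axis of an object. Solidity and the perimeter-to-area value are deposited scores of shape whose scale the sources do not define. Solidity is at most 1 by its usual definition, and here it reached 7.39, so only its differences between sections were compared. Its median over all objects was 6.85 to 6.86 in sections of imaging run 3 and 0.800 to 0.940 in the others. These differences may therefore not measure shape. DAPI and PolyT are deposited intensity values summed over each object, per the file headers, in arbitrary units that can differ between imaging runs. Volumes and positions carry no unit in the files and were taken as µm3 and µm, which fits bounding boxes and section sizes. The filtered versions of the stain columns and the gene reference were not used here.

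Objects with a volume of at least 100 µm3 and at least 10 transcripts were kept as cells, 8865 (CONTROL ICI 3) to 46099 (CONTROL 3) per section. These held 66.1% (CONTROL ICI 1) to 99.2% (CONTROL 3) of each section's assigned transcripts. Totals per section are large, so counting error is small beside the spread between sections. Cells were never treated as replicates. Each section gave 1 value for each of 13 measures: the number of cells and the medians over cells of volume, transcripts, transcripts per 100 µm3, neighbours within 50 µm, solidity, anisotropy, perimeter-to-area value, DAPI and PolyT, then the share of packed cells (at least 12 neighbours within 25 µm) and the ratios of median volume and median transcripts between packed and other cells. Area was the number of 100 µm squares with at least 1 cell, or with at least 1 object for transcripts per mm2.

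Differences of mean log2 section values were tested by two-sided exact permutation of section labels. The ICI effect is the mean of the differences with and without a tumour, permuted within those strata (200 arrangements, smallest p 0.005), and the tumour effect is built likewise over the treatments. The interaction is the difference of the 2 ICI effects, with treatment labels permuted within each tumour state. Its null is thus no ICI effect in either state, not equal effects in both. The 5 comparisons of 2 groups permute 2 groups only, and p cannot go below 0.1. Benjamini-Hochberg adjustment runs over the 13 measures of each contrast. These measures, tests, filters and most alternatives were chosen before the data were examined. The plan also held a test of counts by gene, lists of genes and cell type markers. None of them applies to tables without genes, and none was run.

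Imaging runs were found from the leading digits shared by object identifiers, not from any outcome. Field numbers were contiguous only outside run 3. Run was then used as a further stratum (24 arrangements, smallest p 0.0417), an alternative added after the data were examined, as were leaving out run 3, pooling only the 9 sections with a partner in their run and the sign-flip test of packed against other cells. The other alternatives were no filter on cells, a stricter one (200 µm3 and 50 transcripts), means in place of medians, other definitions of packing, cells per mm2, each section left out in turn and replicate numbers as a block.

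Maps of empty places used pixels of 10 µm. A pixel counted as a gap when it lay inside the tissue outline, at least 200 µm from its edge, and farther from any object centre than 3 times the mean spacing, the square root of area per object. Counting neighbours among all objects, leaving out the filter on transcripts, a distance of 40 µm in every section, neighbours within 2 mean spacings and transcripts per mm2 without nearly silent squares were added after the data were examined. Squares of 100 µm with at least 10 objects were called nearly silent when their transcripts came to less than 10% of the section's median square.

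The tests were tried on simulated data built on the ICI effect on transcripts per cell, with 1000 measures of which 200 were changed. At an unadjusted threshold of 0.05 the test without runs recovered 92.5% of changes of 1 on the log2 scale and 100% of changes of 2, with 0.375% of unchanged measures called. With run as a stratum 77.5% and 99% were recovered, with 4.13% and 4.25% called falsely. Changes smaller than 1 were not simulated, and calls after adjustment were not scored. The ICI effect on transcripts per cell was itself only -0.36 without runs. The recovered shares therefore do not say how often effects of that size would pass, before or after adjustment. Neighbour counts equalled a direct count in 400 of 400 points. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.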

Results

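Hippocampal sections of adult male C57Bl/6 mice were imaged by MERFISH, a method that reads individual RNA molecules in tissue through barcoded fluorescent probes. The labels give 4 groups that cross a tumour with a treatment. CONTROL mice (n = 3 sections) received isotype antibodies, and CONTROL ICI mice (n = 3) received the immune checkpoint inhibitors (ICI) anti-CTLA-4 and anti-PD-1. MELANOMA mice (n = 2) and MELANOMA ICI mice (n = 3) carried intradermal tumours of D4M-3A.UV2, a mouse melanoma cell line, and received isotype antibodies or the same inhibitors. Each of the 11 sections held between 16416 (CONTROL ICI 3) and 119207 (CONTROL ICI 1) segmented objects, and between 349960 (CONTROL ICI 3) and 3164943 (CONTROL 3) assigned transcripts. The tables used here give 1 transcript total per object. Transcripts by gene were not analysed here, so no gene or cell type is named, and the measures below describe how many RNA molecules the cells held, how large they were, how they were packed and how brightly they stained. The labels do not say which animal each section came from, so p-values measure the spread between these sections.

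The sections fell into 3 imaging runs, read from shared leading digits of the object identifiers. Field numbers also continue from section to section in runs 1 and 2, but not in run 3. There CONTROL ICI 3 has 194 fields numbered between 1079 and 1849, a span that encloses MELANOMA ICI 1 (1161 to 1661). Run 1 held CONTROL 1, MELANOMA 1, CONTROL ICI 1, CONTROL ICI 2 and MELANOMA ICI 2. Run 2 held CONTROL 2, MELANOMA 2 and MELANOMA ICI 3, and run 3 held CONTROL 3, CONTROL ICI 3 and MELANOMA ICI 1. Objects of run 3 were of another size class. The median volume of all objects in a section was 1350 to 1515 µm3 in run 3 and 161 to 205 µm3 in runs 1 and 2. Objects with at least 10 transcripts and at least 100 µm3, called cells below, made up 54.0% (CONTROL ICI 3) to 86.1% (CONTROL 3) of objects in run 3 and 11.7% (CONTROL ICI 2) to 32.2% (CONTROL 2) elsewhere. The cells' median volume was 1581 ± 85.0 µm3 in run 3 (SD, n = 3), 817 ± 57.2 µm3 in run 1 (n = 5) and 730 ± 182 µm3 in run 2 (n = 3). Differences between runs took up 87.9% of the variance in log2 cell volume among sections, and differences between the 4 groups 1.53%. For the median number of transcripts per cell these shares were 60.6% and 31.4%. The share of runs was the larger in 11 of 13 measures, but not for cell number (23.6% against 44.3%) or for the volume ratio of packed to other cells (40.2% against 59.4%). Chance alone gives 20% on average for 3 runs and 30% for 4 groups. Every run held sections of at least 3 groups, so most effects below are also given as a mean of differences within runs, a setting chosen after the data were examined. These within-run values rest on 9 of the 11 sections. CONTROL 2 and MELANOMA ICI 1 have no partner in their run for the ICI effect, nor do CONTROL 3 and MELANOMA ICI 3 for the tumour effect.

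The arrangement of objects differed between imaging runs. In run 3 curved bands of closely packed objects stood out, and the 99th percentile of neighbours within 2 mean object spacings was 3.21 to 4 times the section's median. In the 8 sections of runs 1 and 2 this multiple was 2.13 to 2.63. The maps of CONTROL 1 and CONTROL 2 show curved bands empty of objects, and by eye the other 6 maps of these runs show such bands too, though faintly in CONTROL ICI 2. Gaps, places farther than 3 mean object spacings from any object centre, took up 0.372% to 1.66% of the tissue interior in runs 1 and 2. That distance was 31.3 to 39.9 µm there and 62.0 to 67.3 µm in run 3, so shares on this scale were not compared between the runs. At a common distance of 40 µm the shares overlapped, at 0.188% to 1.45% in runs 1 and 2 and 0.435% to 1.52% in run 3, where objects lay farther apart. The highest share was that of CONTROL ICI 3 in run 3, so the share does not measure the empty bands, which rest on the maps alone. The largest connected gap of a section was 177 (CONTROL ICI 2) to 1185 µm (MELANOMA ICI 2) long in runs 1 and 2.

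**Figure D1:**
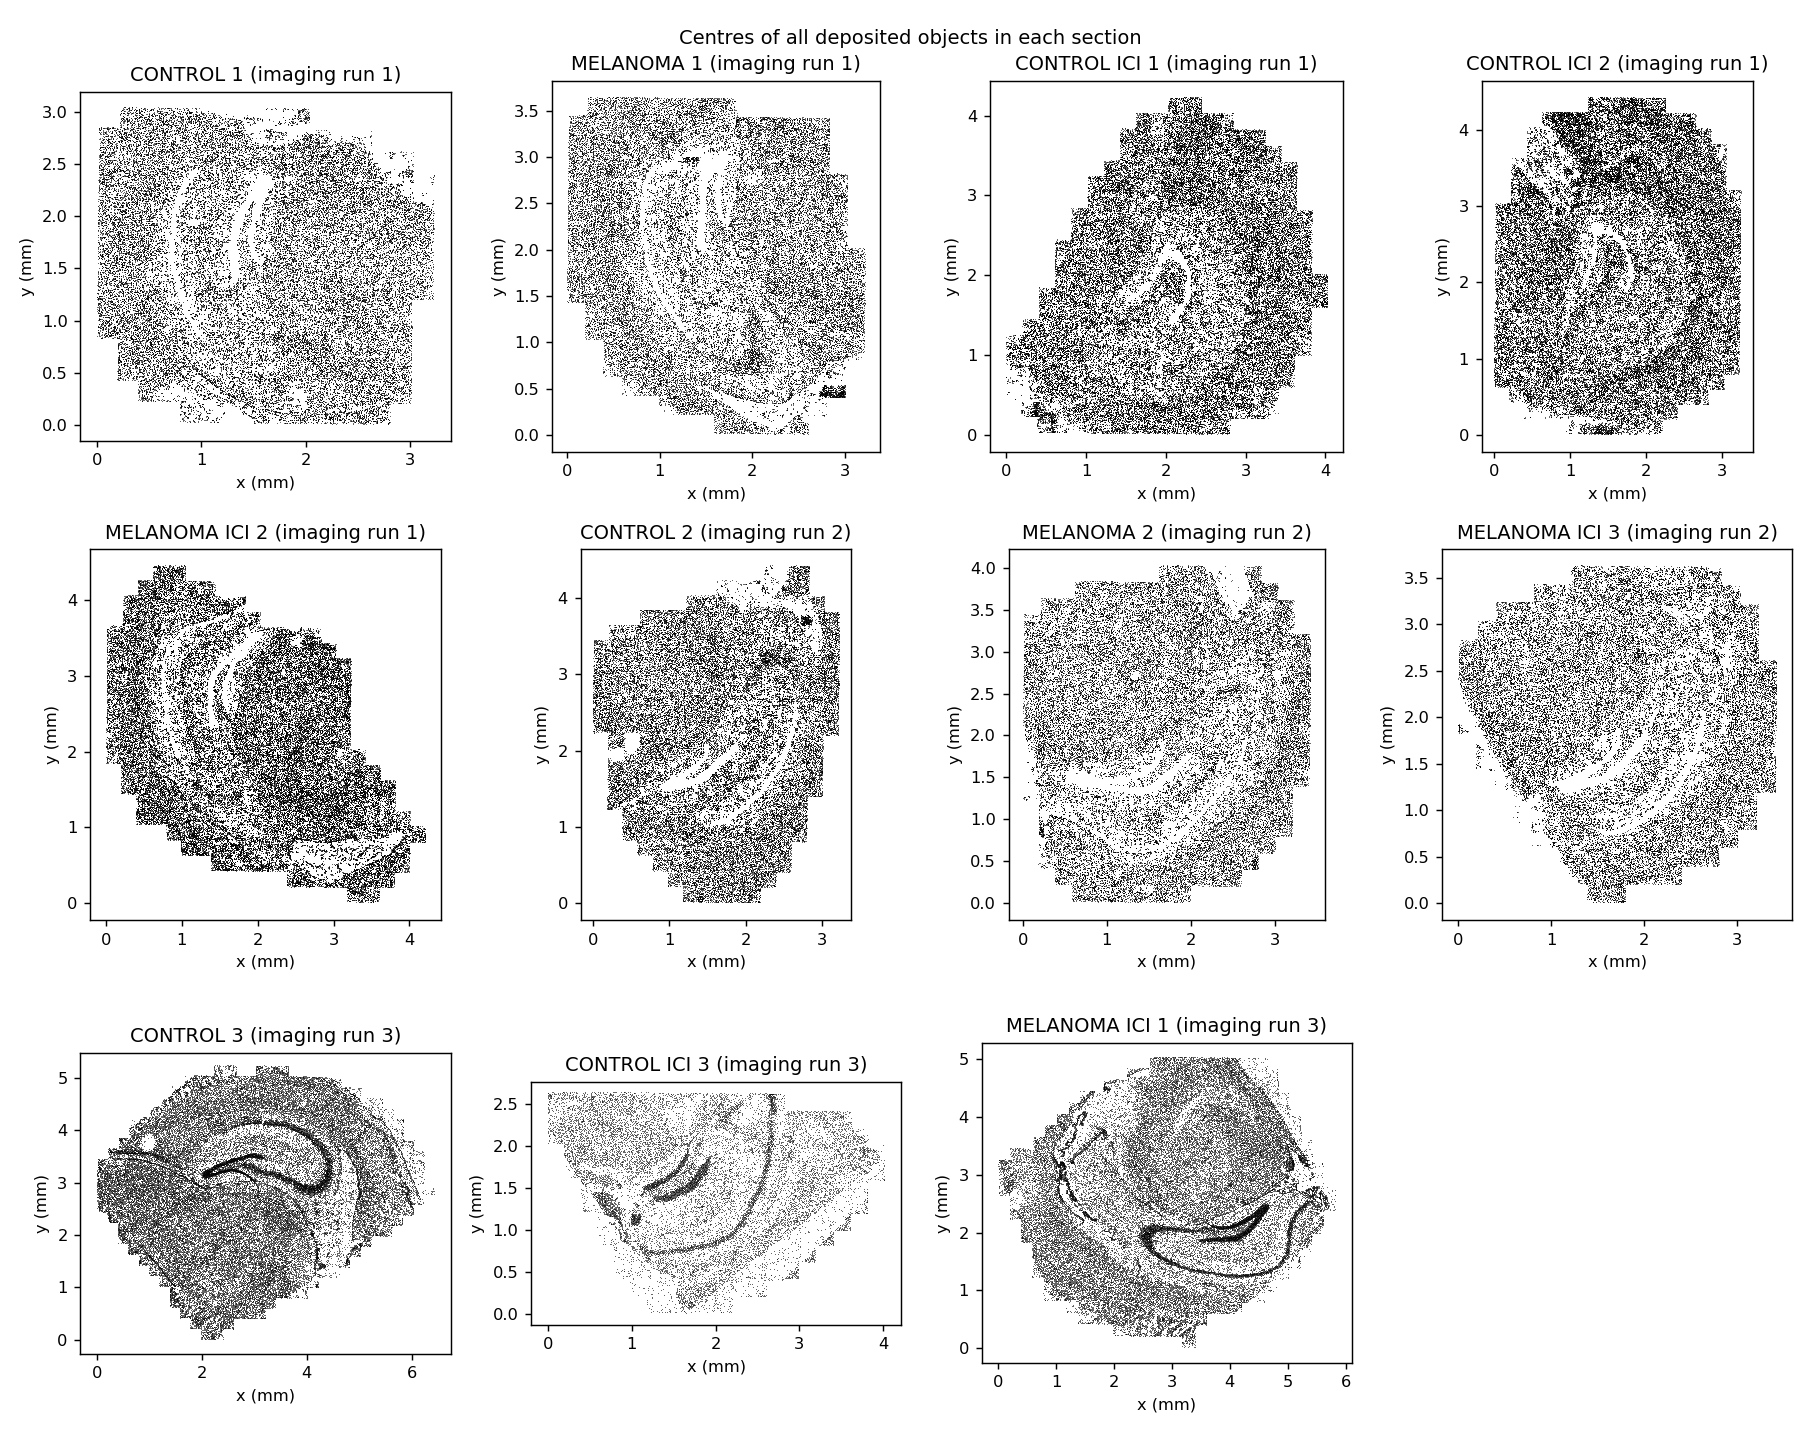
Positions in mm of the centres of all deposited objects in each of the 11 sections, ordered by imaging run, with 1 dot per object and axes scaled separately for each section. The curved bands are empty in CONTROL 1 and CONTROL 2, where gaps took up 1.15% and 1.66% of the interior, and densely filled in CONTROL 3.

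Cells in packed places were smaller than the other cells of their section. A cell counted as packed when at least 12 other cells lay within 25 µm. Packed cells had 0.482 times the median volume of the others (log2 ratio -1.05), with a lower value in 11 of 11 sections, and 1.31 times their median transcripts (log2 ratio 0.39), with a higher value in 11 of 11. Both had p = 0.000977 by a two-sided exact sign-flip test over sections, the smallest p that 11 sections allow. The ratio of transcripts averaged 1.60 in run 3, where CONTROL ICI 3 had medians of 42 and 23, and 1.16 in run 1, where CONTROL 1 had 21.5 and 21. Only small objects can lie so close together, so the definition itself favours a low volume. It also favours transcripts, because the neighbours had passed the filter of 10 transcripts. With neighbours counted among all objects and the densest 10% of cells as packed, packed cells held fewer transcripts in 8 of 8 sections of runs 1 and 2 (0.818 to 0.950 times) and more in 3 of 3 of run 3 (1.16 to 1.56 times). The higher count is thus seen apart from the filter only in run 3. The packed share of cells was 11.3 ± 7.30% in run 3 (n = 3), 1.06 ± 0.713% in run 1 (n = 5) and 2.15 ± 1.09% in run 2 (n = 3), and packed cells of runs 1 and 2 numbered only 84 (CONTROL ICI 2) to 646 (MELANOMA ICI 3) per section.

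The comparison of ICI with isotype antibodies asked whether checkpoint inhibition went with a change in hippocampal cells. ICI sections had fewer transcripts per cell on average, though the difference did not pass the test. Without a tumour the section medians averaged 33.7 ± 14.8 transcripts per cell in CONTROL (SD, n = 3) and 21 ± 4.58 in CONTROL ICI (n = 3). With a tumour they averaged 28 ± 1.41 in MELANOMA (n = 2) and 26.7 ± 7.37 in MELANOMA ICI (n = 3). Over both tumour states the ICI effect was -0.36 on the log2 scale (0.780-fold; exact permutation p = 0.18, Benjamini-Hochberg adjusted over 13 measures 0.78), and -0.19 without CONTROL 3. Within runs the effect was -0.44 (0.736-fold), and ICI sections were lower in 4 of 4 strata, with an exact permutation p of 0.0833 (adjusted 0.722) where 0.0417 is the smallest possible. In run 1 CONTROL 1 had a median of 21 transcripts per cell and CONTROL ICI 1 and 2 had 17 and 20, while MELANOMA 1 had 27 and MELANOMA ICI 2 had 21. In run 2 MELANOMA 2 had 29 and MELANOMA ICI 3 had 24, and in run 3 CONTROL 3 had 50 and CONTROL ICI 3 had 26.

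**Figure D2:**
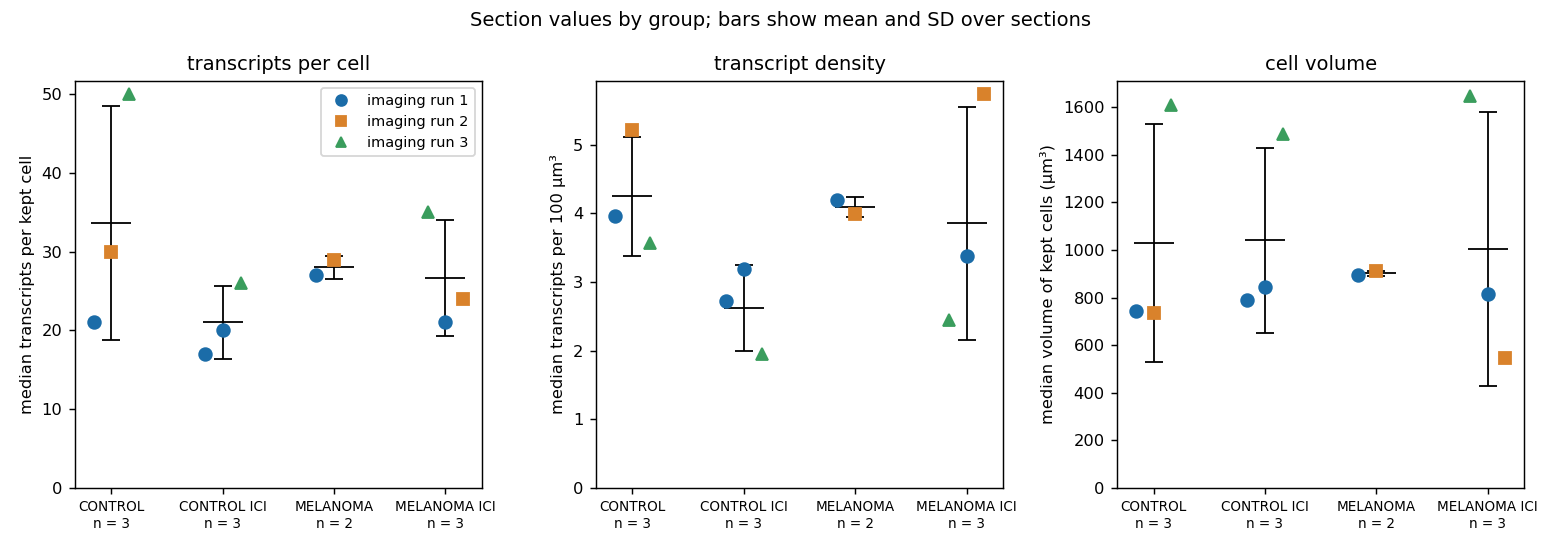
Median transcripts per cell, median transcripts per 100 µm3 and median cell volume in µm3 of each of the 11 sections by group, with 1 symbol per section, colour and shape for the imaging run, and bars for the group mean and SD over sections. Transcripts per cell in CONTROL ICI lie between 17 and 26 and in CONTROL between 21 and 50, and the 3 sections of run 3 have the largest cells.

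Transcripts per unit of cell volume followed the ICI contrast less evenly. The section medians averaged 4.25 ± 0.865 transcripts per 100 µm3 in CONTROL and 2.63 ± 0.627 in CONTROL ICI, with no overlap between the 3 sections of either group, which 10% of splits of 6 sections give by chance. They averaged 4.09 ± 0.151 in MELANOMA and 3.85 ± 1.70 in MELANOMA ICI. The ICI effect was -0.44 on the log2 scale (exact permutation p = 0.135, adjusted 0.78). Within runs it was -0.27 (exact permutation p = 0.417, adjusted 0.75) and lower in 3 of 4 strata. The exception was run 2, where MELANOMA ICI 3 had 1.44 times the density of MELANOMA 2 and 0.601 times its cell volume. Whether the ICI effect differed between mice with and without a tumour was examined through the difference of the 2 effects. Its p-values take no ICI effect in either tumour state as the null, so they are not exact for equal effects. The difference of effects was 0.51 for transcripts per cell (exact permutation p = 0.37) and 0.53 for transcripts per volume (exact permutation p = 0.395), both adjusted to 0.899. Within runs they were 0.25 (exact permutation p = 0.833) and 0.75 (exact permutation p = 0.208). With 1 section left out they ranged from 0.18 to 0.80 and from 0.19 to 0.81.

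The other measures gave no ICI difference past the test. The number of cells per section had an ICI effect of -0.42 (exact permutation p = 0.295, adjusted 0.959), with 27918 ± 16501 cells in CONTROL, 12283 ± 2993 in CONTROL ICI, 19906 ± 2560 in MELANOMA and 23901 ± 9649 in MELANOMA ICI. With 1 section left out the effect ranged from -0.63 to -0.20. Within runs it was -0.65 (exact permutation p = 0.167), which rested on run 3 (-2.38), as the other 3 strata had 0.0099, -0.16 and -0.063. The area of squares with at least 1 cell ranged from 6.18 mm2 (CONTROL ICI 3) to 20.8 mm2 (CONTROL 3). Per area the density averaged 1984 ± 332 cells per mm2 in CONTROL, 1345 ± 114 in CONTROL ICI, 1801 ± 6.92 in MELANOMA and 1753 ± 394 in MELANOMA ICI, an ICI effect of -0.31 (exact permutation p = 0.1) and of -0.28 within runs (exact permutation p = 0.208). The volume of packed relative to other cells had an ICI effect of 0.17 (exact permutation p = 0.135, adjusted 0.78), and ICI sections were higher in 4 of 4 strata within runs (0.17, exact permutation p = 0.125). The within-run value rested largely on run 2 (0.49), as the other strata had 0.0083, 0.060 and 0.10. With means over cells the ICI effect on this ratio, without runs, was -0.0032. Cell volume had an effect of 0.029 and solidity, whose scale is not defined, of 0.10, and within runs they were -0.21 and -0.17. PolyT staining, which marks polyadenylated RNA, had 0.22 and -0.16. The 9 sections of the within-run values gave -0.28, -0.34 and -0.25 without keeping runs apart, so the choice of sections was enough to turn the sign.

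The comparison of tumour-bearing with tumour-free mice asked whether a melanoma in the skin went with a change in the hippocampus. Transcripts per cell had a tumour effect of 0.079 (1.06-fold; exact permutation p = 0.79, adjusted 0.98), and 0.23 within runs (1.17-fold, higher in 3 of 4 strata; exact permutation p = 0.167, adjusted 0.433). The volume of packed relative to other cells had its lowest values in MELANOMA. The ratio averaged 0.402 ± 0.0109 in MELANOMA (n = 2) against 0.499 ± 0.0327 in CONTROL (n = 3), and 0.506 ± 0.0588 in MELANOMA ICI against 0.505 ± 0.0477 in CONTROL ICI. Its tumour effect was -0.15 (exact permutation p = 0.135, adjusted 0.98). Within runs it was -0.18, lower in 4 of 4 strata, with the smallest exact permutation p the design allows, 0.0417, which adjusted to 0.271. Packed cells had medians of 355 µm3 in CONTROL 1, 371 in MELANOMA 1, and 361 in CONTROL 2 and MELANOMA 2. The other cells had 747, 906, 745 and 915, so there the lower ratio went with larger unpacked cells. With ICI, packed cells were smaller in MELANOMA ICI 2 (361) than in CONTROL ICI 1 and 2 (387 and 398). The same held for MELANOMA ICI 1 (903) against CONTROL ICI 3 (931). DAPI staining, which marks DNA and is summed over the cell, had a tumour effect of -0.12 (exact permutation p = 0.75) and within runs it was 0.16, higher in 4 of 4 strata (exact permutation p = 0.0417, adjusted 0.271). The same 9 sections gave 0.25 for DAPI without keeping runs apart, so its sign turned with the choice of sections. DAPI per volume, which was not among the main measures, had a tumour effect of 0.059 (exact permutation p = 0.625). Within runs it was -0.043, lower in 3 of 4 strata (exact permutation p = 0.25). Cell volume had a within-run tumour effect of 0.18, higher in 3 of 4 strata (exact permutation p = 0.167). The within-run rise in summed DAPI was thus not seen per volume.

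Each pair of groups was also compared alone, a setting in which no p below 0.1 is possible. Transcripts per cell had a log2 difference of -0.61 between CONTROL ICI and CONTROL (exact permutation p = 0.2) and -0.10 between MELANOMA ICI and MELANOMA (exact permutation p = 0.8). The differences were -0.17 for MELANOMA against CONTROL (exact permutation p = 0.8), 0.33 for MELANOMA ICI against CONTROL ICI (exact permutation p = 0.4) and -0.28 for MELANOMA ICI against CONTROL (exact permutation p = 0.7). Within runs they were -0.57, -0.32, 0.16, 0.31 and -0.28 in the same order, and the third changed its sign. Without runs, 13 measures in 8 contrasts made 104 tests by exact permutation, of which 0 passed 0.05 after the Benjamini-Hochberg adjustment and 0 before it. Here the comparisons of 2 groups could not pass, and the smallest possible p of the other contrasts was 0.005. At that p 1 measure alone could not pass after adjustment over 13 measures, however large its effect. With run as a stratum 0 of 104 exact permutation tests passed after the adjustment and 2 before it, the tumour effects on packed volume ratio and DAPI. In that setting no comparison of 2 groups can give a p below 0.167, and no other contrast one below 0.0417. A pass after adjustment would need most of the 13 measures at that floor, so the absence of passes was nearly fixed by the design.

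In CONTROL ICI 2 a continuous region at 1 end of the section was nearly without transcripts. Of its 1260 squares of 100 µm, 289 (22.9%) held less than 10% of the transcripts of the section's median square, and 267 of these (92.4%) formed 1 patch. The 289 squares held 29319 objects and 2149 transcripts. In the other 10 sections such squares made up 2.57% to 7.03%. CONTROL ICI 2 also had the largest share of objects with no transcript, 49.8%, which was 34.5% outside those squares. Without CONTROL ICI 2 the ICI effect on transcripts per cell was -0.35.

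**Figure D3:**
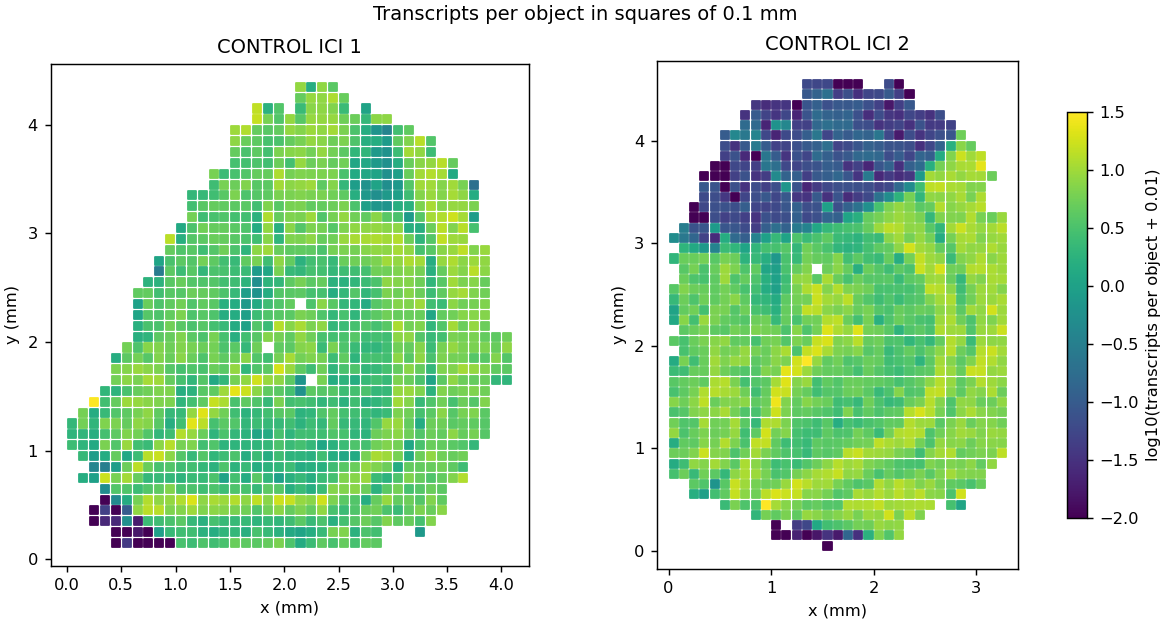
Transcripts per object in squares of 100 µm, on a log10 colour scale, in CONTROL ICI 1 and CONTROL ICI 2 (positions in mm, 1 symbol per square). The dark region at the upper end of CONTROL ICI 2 contains the patch of 267 squares nearly without transcripts.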

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

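The test of patch size was chosen after the result was seen, and the tests of PolyT and DAPI before it. In CONTROL ICI 2, 22.9% of squares of 100 µm were nearly without transcripts, against at most 5.59% in a CONTROL section, and this drew attention because the comparisons of groups do not use where in a section transcripts lie. Missing polyadenylated RNA would lower PolyT staining there, but PolyT per volume in those squares was 0.974 times that of the other squares. No section had a ratio below 0.710 (CONTROL 3), so this test may have been unable to show a loss. PolyT was taken over segmented objects and cannot show missing tissue, but those squares held 1.23 times the objects of other squares. Missing or unfocused nuclei would lower DAPI, but DAPI per volume was 1.28 times that of the rest. Scattered chance lows would not form 1 patch, and 92.4% of the squares did. Smaller patches were also found in CONTROL ICI 1 (26 of 50 such squares) and CONTROL 3 (30 of 61). A local failure of probe hybridisation or of decoding may remain, which these tables cannot test, and no biological explanation was tested.

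CONTROL ICI 3 had 7.03% such squares, also above the highest CONTROL section. They lay apart, with at most 13 of 44 in 1 patch, and held 0.609 times the objects of other squares. PolyT per volume there was 0.798 times and DAPI per volume 0.327 times that of the other squares, so missing or unfocused nuclei are not argued against in this section. DAPI was also low in such squares of CONTROL 2 (0.396), CONTROL 3 (0.169), MELANOMA 1 (0.399) and MELANOMA ICI 1 (0.220), and thus in every section of run 3.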

How the results depend on the processing

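Imaging run as a stratum, the sections with a partner in their run, leaving out run 3, leaving out nearly silent squares, transcripts per mm2, PolyT per volume, the sign-flip test of packed cells, neighbours among all objects and leaving out the filter on transcripts were chosen after the data were examined; the other alternatives, cells per mm2 included, were chosen before. Of 626 alternative values for 37 results, 514 kept their direction and 112 turned it, 50 of them with 1 section left out. Of the 37 results, 14 never turned. Among these are the ICI effect on transcripts per cell (-0.58 with no filter to -0.19 without CONTROL 3) and on transcripts per volume, the tumour effect on packed volume ratio, and the volume of packed against other cells, which kept its exact p below the threshold in every alternative run. Each alternative for that volume still defined packed cells by crowding, which itself favours a low volume. The value of -0.58 with no filter rests on section medians of only 1 to 4 transcripts in runs 1 and 2. In that setting the 2 tumour states went opposite ways, lower with ICI without a tumour and higher with one. The transcripts of packed against other cells had been past the threshold and turned once neighbours were no longer selected by transcripts. No other result was past it after adjustment in any setting, and several settings allow no p that low, so this does not speak for stability. The lowest unadjusted value for the ICI effect on transcripts per cell came with the stricter filter (-0.24, exact permutation p = 0.045, adjusted 0.455; adjusted values over its alternatives ranged from 0.455 to 0.99).

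All values below are log2 differences that turned their direction. With imaging run as a stratum, 12 of 35 results turned. For ICI against its absence the values were -0.21 for cell volume, -0.17 for solidity, 0.0053 for anisotropy and -0.16 for PolyT intensity. For tumour against its absence the values were 0.18 for cell volume, -0.050 for local packing, 0.20 for solidity, -0.010 for anisotropy, -0.013 for perimeter-to-area ratio, 0.16 for DAPI intensity and 0.11 for PolyT intensity. MELANOMA against CONTROL was 0.16 for transcripts per cell. With only the sections that have a partner in their run, runs pooled, 16 of 34 results turned. ICI effects were -0.28 for cell volume, -0.0091 for packed cell share, -0.34 for solidity, 0.025 for anisotropy, 0.017 for perimeter-to-area ratio and -0.25 for PolyT intensity. Tumour effects were 0.25 for cell volume, -0.023 for local packing, 0.24 for packed cell share, 0.041 for packed transcript ratio, 0.36 for solidity, -0.030 for anisotropy, -0.053 for perimeter-to-area ratio, 0.25 for DAPI intensity and 0.20 for PolyT intensity. MELANOMA against CONTROL was 0.16 for transcripts per cell. Without run 3, 11 of 37 results turned. For ICI against its absence the values were -0.15 for cell volume, -0.52 for packed cell share, -0.18 for packed transcript ratio, -0.25 for solidity, 0.011 for anisotropy and -0.0098 for PolyT intensity. For tumour against its absence the values were 0.69 for packed cell share, 0.026 for packed transcript ratio, 0.11 for solidity and -0.011 for anisotropy. MELANOMA against CONTROL was 0.16 for transcripts per cell. With no filter on cells, 5 of 32 results turned. ICI effects were -0.15 for packed cell share and 0.25 for DAPI intensity. Tumour effects were -0.15 for transcripts per cell and 0.40 for packed cell share. MELANOMA ICI against MELANOMA was 0.47 for transcripts per cell. With the stricter filter on cells, 2 of 27 results turned. For ICI against its absence the value was 0.12 for DAPI intensity. MELANOMA against CONTROL was 0.0018 for transcripts per cell. With means over cells, 4 of 31 results turned. ICI effects were -0.0032 for packed volume ratio and -0.030 for packed transcript ratio. Tumour effects were -0.013 for local packing and 0.057 for packed transcript ratio. With the densest 10% of cells as packed, 2 of 6 results turned. For ICI against its absence the value was -0.0066 for packed volume ratio. For tumour against its absence the value was 0.029 for packed transcript ratio. With neighbours among all objects, 1 of 2 results turned. Packed against other cells was -0.0097 for transcripts. With no filter on transcripts, 1 of 2 results turned. Packed against other cells was -0.78 for transcripts.

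With replicate numbers as a replicate block, 8 of 33 results turned. ICI gave 0.18 for DAPI intensity. Tumour effects were 0.072 for cell volume, 0.28 for packed cell share, 0.11 for solidity, -0.0089 for anisotropy, -0.0017 for perimeter-to-area ratio and 0.051 for DAPI intensity. MELANOMA against CONTROL was 0.16 for transcripts per cell. The sections share only a number: correlations of same-numbered sections ranged from -0.71 (MELANOMA ICI 1 with CONTROL 1) to 0.61 (MELANOMA ICI 2 with CONTROL ICI 2), and many lay in different runs. The 3 pairs of CONTROL ICI with CONTROL had 0.54, 0.50 and 0.60, and there transcripts per cell were lower with ICI in all 3 pairs (-0.61, exact sign-flip p = 0.25, the smallest that 3 pairs allow). CONTROL 2 and CONTROL ICI 2 lay in different runs, so their difference cannot be told apart from run. CONTROL 3 and CONTROL ICI 3 both lay in run 3, so the correlations cannot be told apart from run either.

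Leaving out 1 section turned 19 results in at least 1 case. For the ICI effect they span cell volume (-0.19 to 0.22), packed cell share (-0.44 to 0.81), packed transcript ratio (-0.095 to 0.11), solidity (-0.23 to 0.42), anisotropy (-0.065 to 0.011), DAPI intensity (-0.26 to 0.18) and PolyT intensity (-0.065 to 0.50). For the tumour effect they span cell volume (-0.33 to 0.072), transcripts per cell (-0.068 to 0.24), local packing (-0.037 to 0.085), packed cell share (-0.47 to 0.77), packed transcript ratio (-0.098 to 0.11), solidity (-0.54 to 0.13), anisotropy (-0.011 to 0.065), perimeter-to-area ratio (-0.0017 to 0.22) and DAPI intensity (-0.36 to 0.076). For transcripts per cell between 2 groups they were MELANOMA ICI against MELANOMA (-0.32 to 0.051), MELANOMA against CONTROL (-0.47 to 0.16) and MELANOMA ICI against CONTROL (-0.57 to 0.053).

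The stricter filter and packing at 16 neighbours were not run for packed cell share and the packed ratios between groups, nor no filter for the packed transcript ratio, because some sections then had too few packed cells or a median of 0. Between 11.7% (CONTROL ICI 2) and 86.1% (CONTROL 3) of objects passed the filter, so some values rest on a minority of objects.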

Other observations

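The tests in this part were all chosen after the results they bear on were seen, apart from the measures of the main comparisons. Over area rather than per cell, ICI sections held fewer assigned transcripts on average, though the difference did not pass the test after adjustment. Area here was that of squares with at least 1 object. CONTROL sections had 67422, 139101 and 138449 transcripts per mm2, and CONTROL ICI sections 43676, 43167 and 42317, or 45371, 55081 and 44606 without nearly silent squares. MELANOMA sections had 89472 and 106764 and MELANOMA ICI sections 83729, 57481 and 113129. The ICI effect was -0.80 on the log2 scale (0.574-fold; exact permutation p = 0.03), and the adjusted p was 0.51 over the 13 measures and 4 further ones. Within runs it was -0.72, lower in 3 of 4 strata (exact permutation p = 0.0833), and without nearly silent squares it was -0.75 (exact permutation p = 0.04, adjusted 0.51). The exact permutation p rose to 0.113 without MELANOMA 2, to 0.07 without CONTROL ICI 1, 2 or 3 and to 0.167 without run 3. Without MELANOMA ICI 3 the exact permutation p was 0.0167 (adjusted 0.0944). The effect itself stayed between -0.97 and -0.67 with 1 section left out. It was -0.72 without run 3, where the smallest possible p is 0.0556. No test here separates a technical from a biological origin.

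Among the further measures, PolyT per volume had a tumour effect of -0.17 (exact permutation p = 0.255) (-0.30 without MELANOMA 1 to -0.039 without MELANOMA 2), and of -0.064 within runs, lower in 4 of 4 strata (exact permutation p = 0.0417, the smallest possible, adjusted 0.236).

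Transcripts per cell were lower with ICI in 4 of 4 strata within imaging runs, without passing the test. Less polyadenylated RNA would lower PolyT staining per cell too, which differed by -0.16 over the strata with a standard error of 0.20. PolyT per volume differed by 0.039 within runs (-0.043 to 0.19, lower in 2 of 4 strata), so no fall per volume was seen on average. Smaller segmented objects would leave transcripts per volume unchanged, and these differed by -0.27 with a standard error of 0.29. The 2 explanations cannot be told apart, because with 4 strata both standard errors exceed the differences. An ICI effect on the RNA of the probe panel remains an untested possibility.

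By eye, curved bands without objects appear in the maps of runs 1 and 2, faintly in CONTROL ICI 2, and densely packed bands in those of run 3. Whether large merged objects lie across the bands cannot be decided here. Object boxes covered at most 11.2% of the gap area in any section. However, gap area leaves out places near an object's own centre and does not measure the bands. The maps of CONTROL 1 and CONTROL 2, which had neither tumour nor ICI, show the bands too. A candidate explanation is that densely packed cells were lost in segmentation in runs 1 and 2. This was not tested, and images were not analysed here.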
